A study of Mus musculus with 6 samples.

How the data were processed

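Messenger RNA sequencing had been carried out on 6 libraries of mouse bone marrow-derived macrophages, 3 control and 3 treated with recombinant CCL3 for 3 days after 7 days of culture. Total RNA had been extracted with a column kit and libraries built with a SMARTer messenger RNA kit, per the labels' protocols. The description of the design leaves open whether CCL3 was also present in the first culture. How control cells were handled during the 3 days is not given in the sources used here. The authors deposited 1 table of FPKM values (fragments scaled to gene length and library size), with 1 column per library and 54532 genes, together with each gene's length, position and type. The genome build was mm10, per the submitters' processing notes; the aligner, the counting tool, its use of strand, its handling of reads that match several genes and the annotation release are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense genes are therefore uncertain.

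FPKM is already normalized, so no count model was used. FPKM multiplied by gene length was a whole multiple of 1 step per library for 100% of values, within a tolerance of 0.02, which gave the number of fragments per gene. Recovered fragments summed to 18609737, 17913283 and 18539478 in control replicates 1 to 3 and to 17861152, 18058494 and 17399194 in CCL3 replicates 1 to 3. The ratio of this sum to the divisor behind the deposited FPKM was 0.895, 0.851 and 0.868 in control and 1.10, 1.05 and 1.20 with CCL3, so the divisor was not the plain total, and the authors' way of setting it is not given in the sources used here. The choice of divisor shifts the fold changes of well expressed genes by about a common amount, less so those of low genes because of the pseudocount, which moves the number of genes called higher or lower. Before averaging, replicates were compared by the chi-square of their fragments per degree of freedom, which ranged from 27.0 to 128, so no library was a repeat of another and none were merged; this does not show that they came from separate cultures.

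Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 9218 in all and 8465 of them protein coding. Values were taken as log2(FPKM + 1), so a fold change is on that scale and understates the change of low genes. CCL3 was compared with control in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and a variance trend, two-sided tests, Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels are means ± SD over 3 libraries and fold changes carry the standard error of the model. In all, 40 gene lists were fixed before the data were examined, covering antigen presentation, macrophage activation, metabolism, stress, and markers of other cell types. The 33 lists with at least 5 tested members were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 33 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. With an estimated correlation 0 lists passed and with fry 10 lists passed. At an unadjusted p under 0.05, 2 lists passed with an estimated correlation, complement and liver X receptor (camera p = 0.0455 and 0.0376). For each list the members past the threshold were counted over all genes and adjusted over the list alone, and the latter count is given where it differs.

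Genes were named by a rule also fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among protein-coding genes past the threshold whose libraries did not overlap between groups, and up to 4 members past the threshold from each list, or up to 2 given as values where none passed. It added genes of interest, among them Ccl3, Ccr1, H2-Ab1, Cd74, H2-K1, B2m, Cd80, Cd86, Cd40, Cd274, Arg1, Mrc1, Nos2, Il1b and Tnf. Genes named outside this rule were H2-Aa, H2-Eb1, Nlrc5, Psme2, H2-M3, Ccl22 and the genes of an ERK list.

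The steps were tested on simulated data. Fragments were drawn for the real genes from a negative binomial with their mean levels, the deposited divisors as library sizes and the median dispersion of the real libraries, with 200 genes changed between CCL3 and control. Of genes changed 4-fold 100.0% were recovered with the right sign, of genes changed 2-fold 84.8%, and of genes changed 1.5-fold 24.2%, over 9219 tested genes, and 8.61% of calls were on unchanged genes, more than the nominal 5%. With a simulated GC trend between the groups 2406 unchanged genes were called over 9240 tested genes, and 20 over 9234 after GC correction, 12.7% of the calls there. Each setting was simulated once. In a further simulation with the complement list raised 2-fold, camera called that list and 0 others. Genes were drawn independently, whereas the estimated correlation in the real data reached 0.893 in the cell cycle list. This simulation therefore does not test false calls of lists with correlated genes. The simulated GC trend was the same in all libraries of a group, unlike in the real libraries. It was also a straight line in GC content. The real median log2 fold change was -0.02 in the lowest GC decile, -0.29 in decile 4 and 0.51 in decile 10. The simulation therefore does not show how many real calls follow from GC content, or how well the correction removes the real trend.

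Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.01, no filter on low values or a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, rescaling to TPM, no variance trend, array weights, the replicate number as a block, protein-coding genes only, a change of at least 2-fold and leaving out each library in turn. Added after the data had been seen were a correction for GC content, for GC content and gene length together, GC correction with the block, plain fragment totals as divisor, limma's voom on recovered fragments, and leaving out both replicates numbered 3. GC content was the median over a gene's transcripts in the GENCODE M21 annotation of GRCm38, which gave a value for 9212 of 9218 tested genes. The correction removed, per library, a loess curve, with a span of 0.4, fitted to the deviation from each gene's mean.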

Results

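Messenger RNA was measured in cultured mouse macrophages grown from bone marrow of C57BL/6J mice, an inbred laboratory strain. Cells had been cultured for 7 days, after which recombinant CCL3, a chemokine, was added for 3 days. The description of the design can also be read as CCL3 being present in the first culture as well. The data comprised 3 control and 3 CCL3 libraries, each with 1 FPKM value per gene, that is, fragments scaled to gene length and library size. Fragments recovered from the deposited values came to between 17399194 and 18609737 per library, and the median tested gene had between 381 and 595 fragments in a library. The labels do not say whether the libraries came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The title of the series sets the comparison in the context of antigen presentation by macrophages.

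CCL3-treated macrophages differed from control macrophages across a large part of the expressed genes. The folate receptor gene Folr2, the complement genes C1qa, C1qb and C1qc, the invariant chain gene Cd74 and the lipid transport gene Apoe were higher with CCL3, while Tnf, the lipopolysaccharide co-receptor gene Cd14, the inflammasome gene Nlrp3 and the dendritic and B cell activation marker Cd83 were lower. Of 9218 genes tested with limma, 2990 passed an adjusted p of 0.05, 1655 of them higher and 1335 lower with CCL3. Among these, 502 genes rose and 235 fell by at least 2-fold on the log2(FPKM + 1) scale. The values of the 3 CCL3 libraries lay entirely above or below those of the 3 control libraries for 48.6% of tested genes, where chance gives 10%. The direction split depended on scaling: 55.4% of calls were higher with FPKM as deposited, 11.3% after rescaling to TPM and 20.9% with plain fragment totals. TPM scaling and plain totals moved the median log2 fold change of all tested genes from 0.01 to -0.48 and -0.28. With median-ratio scaling and quantile normalization this median was -0.008 and -0.014, and 54.0% and 51.5% of calls were higher. The count of calls also varied when 1 library was left out. It was 1643, 1128 and 3142 without control replicates 1, 2 and 3. Without CCL3 replicates 1, 2 and 3 it was 2708, 2599 and 1921. In each case 0 of the original calls that could still be tested changed sign.

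The first principal component held 65.6% of the variance and separated the CCL3 libraries from the control libraries. Control replicate 3 stood apart from the other control libraries, with a first component score of -16.3 against -33.3 and -33.2, and a second component score of 25.4. Pearson correlations across genes were 0.968 to 0.990 within control, 0.978 to 0.980 within CCL3 and 0.921 to 0.963 between groups. Genes are not independent replicates in such a correlation. Genes above 0 numbered 16394 to 16802 in control and 15035 to 15451 with CCL3, and the share of ribosomal RNA fragments was 0.175% to 0.201% and 0.225% to 0.314%. Without both replicates numbered 3, left out after the data had been seen, 2647 genes passed, and 2271 of the 2978 original calls that could still be tested passed again in the same direction.

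**Figure D1:**
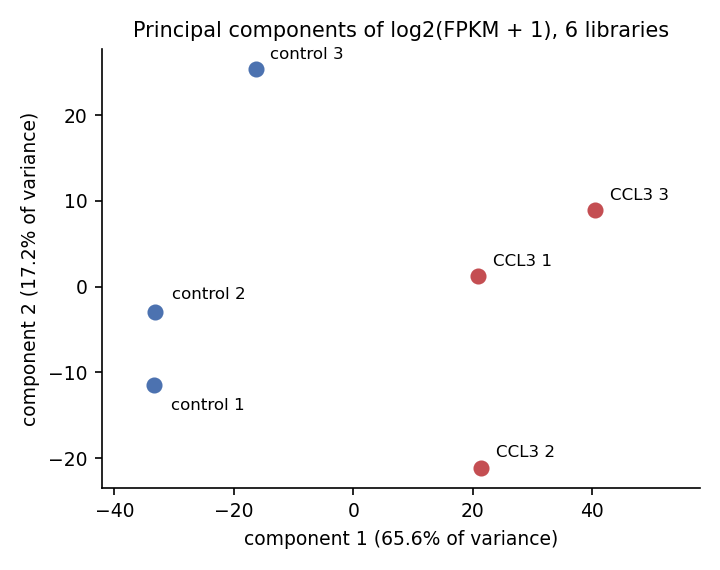
First 2 principal components of log2(FPKM + 1) over 9218 genes, with 1 point per library and the share of variance on each axis. The 3 CCL3 libraries (red) lie between 20.9 and 40.5 on component 1, and the 3 control libraries (blue) between -33.3 and -16.3.

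Folr2 showed the largest rise of the genes the naming rule covers, from 4.69 ± 1.50 to 31.1 ± 2.0 FPKM (mean ± SD, n = 3 per group). Its log2 fold change was 2.53 ± 0.20 SE, with an adjusted p of 0.00242 (limma), and its mm10 record is ENSMUSG00000032725, chromosome 7, 101839988 to 101857194. The secreted protease inhibitor gene Slpi rose by 2.22 ± 0.25 SE, and the nucleotide synthesis gene Tk1 by 2.15 ± 0.58 SE with control replicate 3 close to the CCL3 libraries. The osteoclast proton pump gene Atp6v0d2 (log2 fold change 2.09), the lipid peroxide reductase gene Gpx4 (2.01), the heparan sulfate proteoglycan gene Sdc1 (1.97), the Src family kinase gene Fgr (1.99) and the tubulin gene Tuba1b (2.02) also ranked among the 12 largest rises. The remainder were the ribosomal protein gene Rplp1, with a log2 fold change of 2.12, Nrgn with 2.10, the translation elongation factor gene Eef1a2 with 2.04 and the nucleoside diphosphate kinase gene Nme4 with 2.01. As with Tk1, control replicate 3 lay close to the CCL3 libraries for Tuba1b, at 671 FPKM against 748 in CCL3 replicate 2. Genes with close copies in the genome, such as the ribosomal protein and tubulin genes, are uncertain because the authors' handling of shared reads is not given in the sources used here.

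Tmem273 fell furthest of these genes, from 47.9 ± 1.54 to 6.73 ± 0.752 FPKM (mean ± SD, n = 3 per group). Its log2 fold change was -2.67 ± 0.13 SE with an adjusted p of 0.000280 (limma), and its record is ENSMUSG00000041707, chromosome 14, 32785963 to 32817984. The kallikrein gene Klk1b11 changed by -2.49 ± 0.34 SE and the surface antigen gene Ly6a by -2.40 ± 0.39 SE, both from gene families with similar members. The C-type lectin gene Clec4n had a log2 fold change of -2.10, and Cd83 of -1.91. Negative regulators of ERK kinase signalling were among the 12 largest falls, with log2 fold changes of -1.94 for the phosphatase gene Dusp6 and -1.83 for Spry2. The vascular growth factor gene Vegfa (-1.77), the costimulatory ligand gene Tnfsf9 (-1.81), the cold-induced RNA binding protein gene Rbm3 (-1.87), Cd24a (-1.88) and Ms4a6d (-1.79) completed that group. Adjusted p over the 24 largest changes ranged from 0.000280 to 0.0269.

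Several genes of antigen presentation were higher in CCL3-treated macrophages, while 0 of 6 tested costimulation genes rose. Over all genes 1655 of 9218 rose, so 0 of 6 can easily arise by chance. The other 6 of 12 costimulation genes were below the filter, and the difference between the groups of genes was not tested. Cd74, whose product chaperones MHC class II molecules, rose from 438 ± 94.4 to 1246 ± 164 FPKM (log2 fold change 1.52 ± 0.20 SE, adjusted p = 0.00315; ENSMUSG00000024610, chromosome 18, 60803848 to 60812646). The peptide loading genes H2-DMa (1.06 ± 0.15 SE) and H2-DMb1 (0.81 ± 0.12 SE) and the lysosomal thiol reductase gene Ifi30 (0.86 ± 0.16 SE) rose with it. In the class II list 4 of 11 tested members rose and 0 fell, against 2 and 0 with TPM scaling and 4 and 0 with plain totals. H2-Ab1 did not pass (log2 fold change 0.55 ± 0.23 SE, adjusted p = 0.10). H2-Aa and H2-Eb1, singled out after their values were seen, had log2 fold changes of -0.00292 ± 0.30 SE and -0.24 ± 0.35 SE. The list's median log2 fold change was 0.33, and -0.18 with TPM scaling and -0.03 with plain totals, which lower the median of all genes; relative to other genes the list passed as higher there (camera adjusted p = 0.0295 and 0.0330). The median was 0.19 after GC correction and 0.06 after GC and length correction (adjusted p = 0.110 and 0.164). With FPKM as deposited camera gave an adjusted p of 0.0688, short of the threshold (adjusted p = 0.662 with an estimated correlation). It passed without control replicate 2 (adjusted p = 0.0276) and without CCL3 replicate 3 (adjusted p = 0.0117). Leaving out 1 library moved the list's median log2 fold change, from 0.21 without control replicate 3 to 0.59 without control replicate 1.

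In the MHC class I list, 10 of 20 tested members rose and 3 fell, against 0 and 5 with TPM scaling and 3 and 3 with plain totals. The light chain gene B2m rose from 992 ± 122 to 1926 ± 493 FPKM (log2 fold change 0.93 ± 0.20 SE, adjusted p = 0.0126), the heavy chain gene H2-D1 by 0.86 ± 0.16 SE and H2-K1 by 0.64 ± 0.14 SE. The immunoproteasome genes Psmb8 and Psmb9 rose by 0.96 ± 0.23 SE and 0.83 ± 0.21 SE. The 3 members that fell, named after their values were seen, were the class I transactivator gene Nlrc5 (-0.76), the proteasome activator gene Psme2 (-0.64) and H2-M3 (-0.56). The list's median log2 fold change was 0.45, and -0.08 with TPM scaling, which lowers the median of all genes (camera adjusted p = 0.166, direction up). After quantile normalization it was -0.01, where the fold change of H2-K1 also changed sign, and after GC and length correction 0.22 (adjusted p = 0.164). Camera did not call the list (adjusted p = 0.0688, and adjusted p = 0.662 with an estimated correlation), though it passed without control replicate 2 (adjusted p = 0.0458) and without CCL3 replicate 3 (adjusted p = 0.0334). H2 genes resemble one another closely, so their levels are uncertain. Markers of dendritic cells moved with these groups at low levels: 3 of 3 tested markers rose, Ccr7 from 0.402 ± 0.263 to 1.62 ± 0.236 FPKM, Batf3 from 1.45 ± 0.129 to 3.55 ± 0.954 FPKM and Fscn1 from 1.17 ± 0.901 to 3.49 ± 0.837 FPKM, while 12 others of the list were below the filter.

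**Figure D2:**
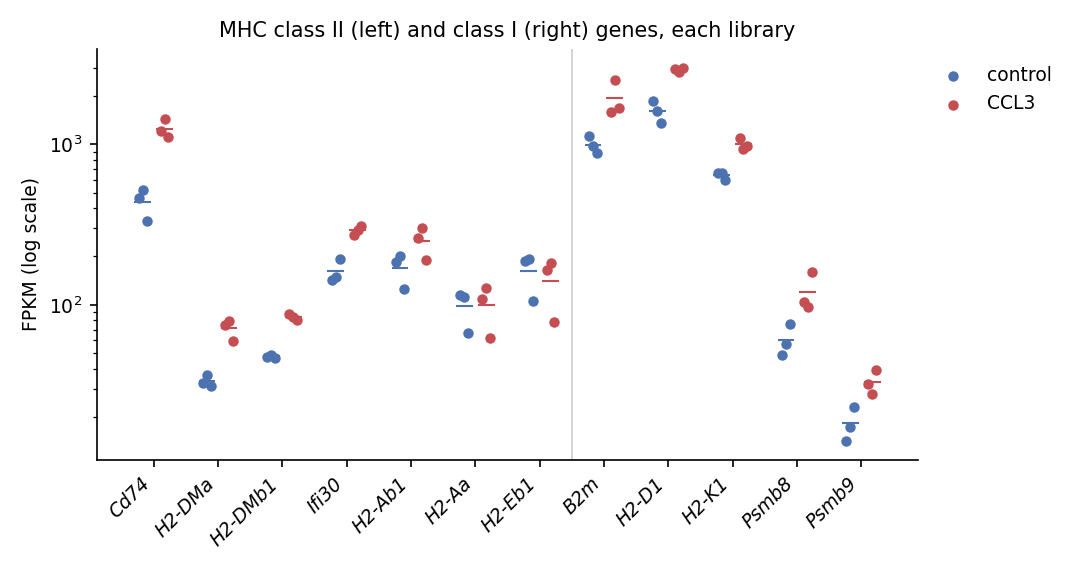
FPKM on a log axis for MHC class II genes (left of the line) and class I genes (right), with 1 point per library and a bar at each group mean of 3 libraries. Cd74 lies between 1109 and 1428 FPKM with CCL3, against at most 519 in control, while the points of H2-Aa and H2-Eb1 overlap.

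Of the T cell costimulation list, 0 of 6 tested members rose and 3 fell: Cd83 from 29.5 ± 10 to 6.95 ± 1.83 FPKM, Tnfsf9 from 7.32 ± 3.52 to 1.27 ± 0.522 FPKM and the ICOS ligand gene Icosl from 7.66 ± 0.925 to 3.72 ± 1.19 FPKM. Rises and falls were 0 and 4 with TPM scaling and 0 and 3 with plain totals. Camera did not call this list (adjusted p = 0.272), while fry called it as lower (adjusted p = 0.0233). Cd40 had 1.58 ± 0.435 FPKM in control and 2.33 ± 0.600 with CCL3 and did not pass (log2 fold change 0.37 ± 0.19 SE, adjusted p = 0.165). Cd80 and Cd86, which encode the ligands of CD28, were below the filter, at 0.402 ± 0.0435 and 0.442 ± 0.139 FPKM in control and 0.645 ± 0.313 and 0.433 ± 0.143 with CCL3. Among inhibitory ligands and receptors 1 of 10 tested members rose, Vsir (0.64 ± 0.14 SE), and 3 fell, Lilrb4a (-1.50 ± 0.25 SE), Pvr (-0.62 ± 0.14 SE) and Lair1 (-0.59 ± 0.18 SE). Cd274, which encodes PD-L1, did not pass (log2 fold change -0.06 ± 0.29 SE, adjusted p = 0.881). Camera gave the inhibitory list an adjusted p of 0.900, and its rises and falls were 0 and 4 with TPM scaling and 0 and 3 with plain totals.

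The few inflammatory mediators that could be tested were more often lower than higher with CCL3, and 12 of the list's 18 members were below the filter. Of 6 tested members 3 fell, Tnf (log2 fold change -1.19 ± 0.26 SE, adjusted p = 0.0130), Cd14 (log2 fold change -0.94 ± 0.18 SE, adjusted p = 0.00783) and the itaconate synthesis gene Acod1 (log2 fold change -0.90 ± 0.28 SE, adjusted p = 0.0432), and 1 rose, the acute phase gene Saa3 (log2 fold change 1.34 ± 0.33 SE, adjusted p = 0.0182). Rises and falls were 1 and 4 with TPM scaling and 1 and 4 with plain totals, and camera did not call the list (adjusted p = 0.272). Il1b was below the filter, at 1.08 ± 0.874 FPKM in control and 0.187 ± 0.171 with CCL3. Nos2 and Arg1, classical markers of opposite activation states, had at most 2 fragments per library, and no fold was computed. Nlrp3, the sensor of an inflammasome, fell from 17.4 ± 1.85 to 4.50 ± 0.991 FPKM (log2 fold change -1.76 ± 0.17 SE, adjusted p = 0.00310), while the pyrin gene Mefv rose by 1.25 ± 0.27 SE, the 1 fall and 1 rise among 10 tested inflammasome members. In the interferon-stimulated list 1 of 21 members rose, Ifi204 (0.89 ± 0.24 SE), and 0 passed when adjusted over the list alone; in the interferon-gamma list 0 of 9 passed. With TPM scaling 6 and 3 members of these lists fell and 0 rose, with plain totals 4 and 2, and for the inflammasome list rises and falls were 1 and 3 with TPM scaling and 1 and 3 with plain totals. With FPKM as deposited camera gave these lists adjusted p values of 0.878, 0.878 and 0.878.

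Chemokine genes moved in both directions. Ccl5 (1.10 ± 0.17 SE), Cxcl16 (1.28 ± 0.15 SE) and Ccl22 (0.78 ± 0.20 SE, named after its value was seen) made up the 3 of 12 tested members that rose, and Ccl7 (-1.33 ± 0.21 SE) and Ccl9 (-1.20 ± 0.24 SE) the 2 that fell, or 3 when adjusted over the list alone. Rises and falls were 2 and 5 with TPM scaling and 3 and 4 with plain totals. The gene of the added chemokine itself, Ccl3, stood at 33.9 ± 7.43 FPKM in control and 40.1 ± 10.7 with CCL3, a difference within the replicate spread (log2 fold change 0.23 ± 0.23 SE, adjusted p = 0.477). The receptor gene Ccr1 was below the filter, at 1.14 ± 0.187 FPKM in control and 0.703 ± 0.478 with CCL3. Of 6 tested receptor genes 1 rose, Ccr7 (0.91 ± 0.17 SE), and 1 fell, the fractalkine receptor gene Cx3cr1 (-0.82 ± 0.15 SE). Camera gave adjusted p values of 0.900 and 0.900 for the chemokine and receptor lists.

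Complement genes of the C1q complex, which tags targets for uptake, rose together. C1qa rose from 326 ± 47.0 to 1003 ± 70.8 FPKM (log2 fold change 1.62 ± 0.16 SE, adjusted p = 0.00310; ENSMUSG00000036887, chromosome 4, 136895917 to 136898803), C1qb by 1.11 ± 0.14 SE and C1qc by 1.22 ± 0.13 SE, and the complement receptor gene Vsig4 by 0.97 ± 0.26 SE at low levels. In all, 4 of 8 tested members rose and 0 fell, against 3 and 1 with TPM scaling and 4 and 1 with plain totals. Camera called the list as higher (adjusted p = 0.0457), which was lost with an estimated correlation (adjusted p = 0.662). It was also lost without control replicate 3, CCL3 replicate 1 or CCL3 replicate 2 (adjusted p = 0.101, 0.0820 and 0.0929). The estimated correlation was -0.0165, below the preset 0.01, and the unadjusted camera p with it was 0.0455. Of 17 tested phagocytosis and Fc receptor genes 6 rose and 2 fell, among them the scavenger receptor gene Cd36 (1.54 ± 0.33 SE), the integrin gene Itgax (1.20 ± 0.30 SE), the adaptor gene Tyrobp (0.99 ± 0.14 SE) and Clec4n, but rises and falls were 3 and 6 with TPM scaling and 5 and 5 with plain totals. Genes of alternative activation were mixed, with 5 risen and 2 fallen of 12: Folr2, Tgfb1 (1.09 ± 0.14 SE) and the mannose receptor gene Mrc1 (log2 fold change 0.84 ± 0.15 SE, adjusted p = 0.00643) rose, while Klf4 (-1.27 ± 0.23 SE) and the haemoglobin scavenger receptor gene Cd163 (-0.92 ± 0.17 SE) fell. Rises and falls of this list were 2 and 4 with TPM scaling and 5 and 3 with plain totals. Camera did not call the latter lists (adjusted p = 0.513 and 0.317), while fry called alternative activation as higher (adjusted p = 0.0156). Among 18 macrophage identity genes 6 rose, including Cebpa (1.15 ± 0.21 SE), and 2 fell, Cd14 and the lysozyme gene Lyz2 (-0.91 ± 0.26 SE), with a camera adjusted p of 0.505, and rises and falls were 2 and 8 with TPM scaling and 3 and 3 with plain totals, and 2 and 1 after GC and length correction.

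Genes of lipid transport under the liver X receptor rose in part, and genes of cholesterol synthesis fell more often than they rose. Apoe rose from 5710.2 ± 2792 to 18315 ± 2365 FPKM (log2 fold change 1.81 ± 0.36 SE, adjusted p = 0.00934; ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), with control replicates spread from 2862 to 8443 FPKM. The receptor gene Nr1h3 rose by 1.57 ± 0.18 SE, the lipoprotein lipase gene Lpl by 1.56 ± 0.19 SE and Apoc1 by 1.41 ± 0.35 SE. In this list 8 of 15 tested members rose, 9 when adjusted over the list alone, and 0 fell, against 4 and 2 with TPM scaling and 6 and 1 with plain totals. Camera called it as higher (adjusted p = 0.0455), which was lost with an estimated correlation (adjusted p = 0.662) and after GC correction alone (adjusted p = 0.0525). The estimated correlation was -0.0394, and the unadjusted camera p with it was 0.0376. GC correction lowered the list's median log2 fold change from 0.67 to 0.27 and its rises to 4, and after GC and length correction the list passed (adjusted p = 0.0392). It was also lost without control replicate 3, CCL3 replicate 1 or CCL3 replicate 2 (adjusted p = 0.123, 0.0820 and 0.0929), and over all alternatives its adjusted p ranged from 0.00457 to 0.662. In the cholesterol synthesis list 6 of 18 members fell and 2 rose, or 7 and 3 when adjusted over the list alone, and falls and rises were 14 and 1 with TPM scaling and 13 and 1 with plain totals. Insig1 (-1.69 ± 0.17 SE) and Cyp51 (-1.18 ± 0.16 SE) fell, and Mvk rose (1.23 ± 0.22 SE). Camera fell short for it (adjusted p = 0.0688, and adjusted p = 0.662 with an estimated correlation), while fry called it as lower (adjusted p = 0.0163).

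Cell cycle genes had higher means with CCL3, but control replicate 3 overlapped the CCL3 libraries. Mki67 rose from 1.99 ± 1.14 to 8.15 ± 2.22 FPKM (log2 fold change 1.65 ± 0.28 SE, adjusted p = 0.00549), and Top2a, E2f1 and Tpx2 by 1.52 ± 0.34 SE, 1.50 ± 0.44 SE and 1.21 ± 0.39 SE. Of 29 tested members 6 rose, 4 when adjusted over the list alone, and 0 fell, against 4 and 0 with TPM scaling and 5 and 0 with plain totals. Without control replicate 3, 22 of 29 rose, and without both replicates numbered 3, 14 of 28. The list's median log2 fold change was 0.80, 1.23 without control replicate 3 and 0.46 without control replicate 1. The mean log2(FPKM + 1) of the list was 2.52, 3.07 and 4.16 in the control replicates 1 to 3 and 4.04, 3.68 and 4.51 in the CCL3 replicates. Camera called the list as higher (adjusted p = 0.00548), which was lost with an estimated correlation (adjusted p = 0.880) and without control replicate 1 (adjusted p = 0.0666), with a range from 4.53e-08 to 0.880 over all alternatives. Mitochondrially encoded genes, which hold subunits of the respiratory chain, rose in 8 of 12 tested cases, 10 when adjusted over the list alone, and 0 fell, against 5 and 0 with TPM scaling and 8 and 0 with plain totals. The median log2 fold change with TPM scaling was 0.49. Their share of all fragments overlapped between groups, 0.356% to 0.496% in control and 0.444% to 0.756% with CCL3. The log2 fold changes were 1.50 ± 0.22 SE for mt-Nd6, 1.44 ± 0.22 SE for mt-Atp6, 1.37 ± 0.32 SE for mt-Nd4 and 1.26 ± 0.19 SE for mt-Co3. Control means were uneven, at 9.86 FPKM for mt-Atp6, 13.5 for mt-Co3, 88.3 for mt-Nd6 and 135 for mt-Nd4. The authors' handling of reads that match several genes is not given in the sources used here, so these levels and changes are uncertain. Camera called this list (adjusted p = 0.000671), which was lost with an estimated correlation (adjusted p = 0.662). Nuclear genes of oxidative phosphorylation were mixed, with 7 risen and 5 fallen of 26, or 10 and 6 when adjusted over the list alone (camera adjusted p = 0.417), but 4 and 10 with TPM scaling and 4 and 8 with plain totals.

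Genes of the antioxidant response fell more often than they rose. Of 15 tested members 7 fell and 2 rose, or 8 and 3 when adjusted over the list alone, against 10 and 1 with TPM scaling and 9 and 2 with plain totals. The peroxiredoxin gene Prdx1 (-1.30 ± 0.17 SE), Nqo1 (-1.25 ± 0.26 SE) and the glutathione synthesis gene Gclc (-1.05 ± 0.14 SE) fell, while the ferritin light chain gene Ftl1 rose (1.63 ± 0.20 SE). Immediate early genes fell in 5 and rose in 3 of 13 tested cases, with 6 falls when adjusted over the list alone. Falls and rises were 8 and 0 with TPM scaling and 8 and 2 with plain totals, and 6 and 1 after GC correction. Dusp1 (-1.16 ± 0.20 SE), Fos (-1.05 ± 0.20 SE), Btg2 (-1.03 ± 0.21 SE) and Egr1 (-0.92 ± 0.18 SE) were lower. In the stress response list 3 of 18 members fell, the transcription factor genes Atf4 (-0.97 ± 0.19 SE), Ddit3 (-0.61 ± 0.14 SE) and Xbp1 (-0.58 ± 0.13 SE), and 1 rose, the chaperone gene Hsp90b1 (1.02 ± 0.22 SE), against falls and rises of 9 and 0 with TPM scaling and 6 and 1 with plain totals. With FPKM as deposited camera called none of these lists (adjusted p = 0.168, 0.317 and 0.365). The immediate early list passed as lower after GC correction (adjusted p = 0.0401, median log2 fold change -0.57 against -0.39) and after GC and length correction (adjusted p = 0.0173), within a range from 0.0173 to 0.796 over all alternatives, the adjusted p being 0.796 with an estimated correlation.

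**Figure D3:**
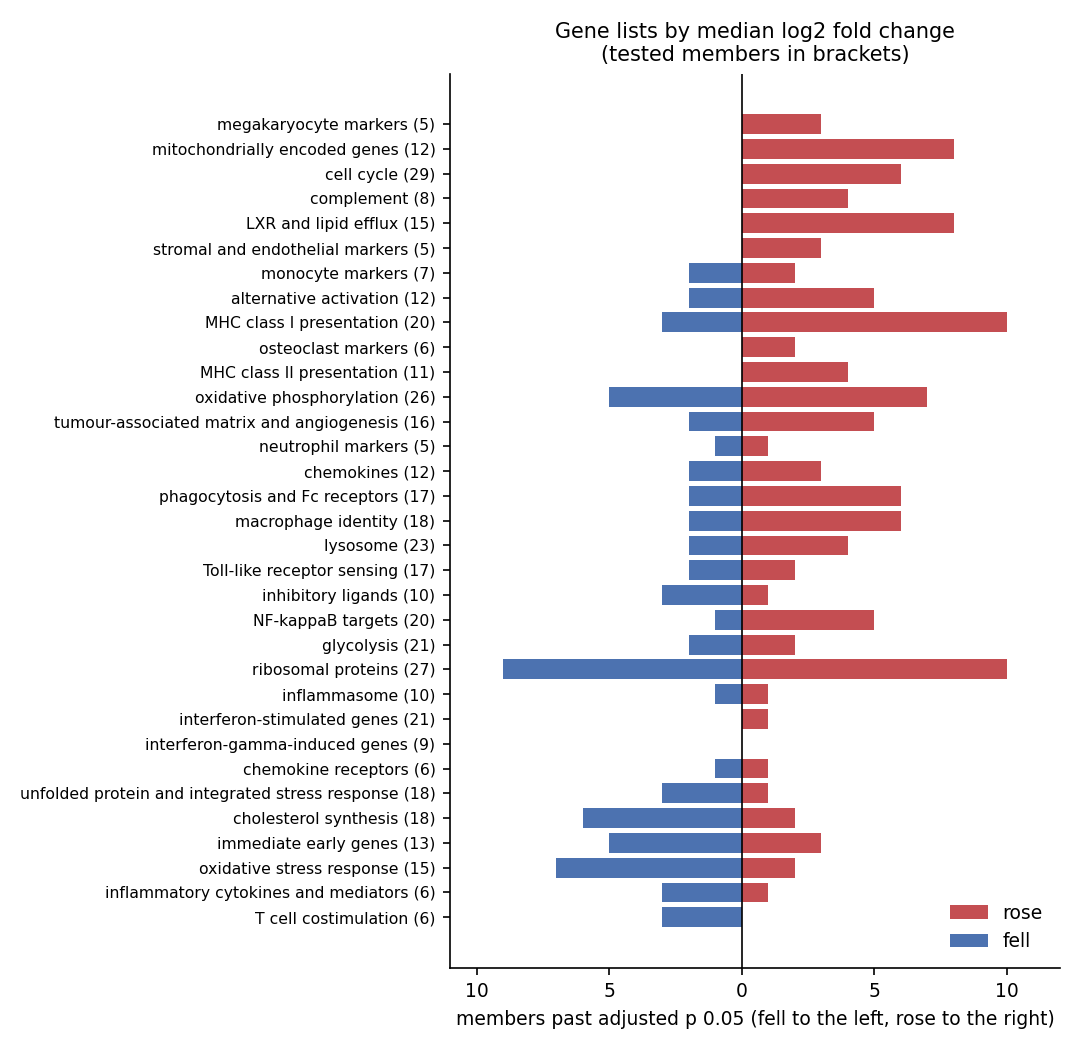
Number of members past an adjusted p of 0.05 in the 33 gene lists tested, with falls to the left and rises to the right. Tested members stand in brackets, and lists are ordered by median log2 fold change. The MHC class I list has 10 rises and 3 falls with FPKM as deposited, as drawn, against 0 and 5 with TPM scaling and 3 and 3 with plain totals.

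Fold change followed the GC content of genes, which limits many of the groups above, while the cell cycle, mitochondrial, complement and liver X receptor lists passed after GC and length correction with the preset correlation of camera (adjusted p = 0.000430, 6.02e-06, 0.0211 and 0.0392). Before correction, none of these lists passed camera with an estimated correlation (adjusted p = 0.880, 0.662, 0.662 and 0.662). That correlation was 0.893 in the cell cycle list and 0.598 in the mitochondrial list. In the complement and liver X receptor lists it was -0.0165 and -0.0394, below the preset 0.01. Correlated genes were therefore not what removed the complement and liver X receptor calls. Median GC content was 56.5% for genes that rose and 49.0% for genes that fell, and after a GC correction chosen once the data had been seen 1738 of 2987 calls passed in the same direction. With GC and gene length removed together, Apoe, Apoc1, H2-K1, Acod1, Cebpa, Lyz2, E2f1, Batf3, Fscn1, Lair1 and Vsir among the genes above no longer passed (adjusted p from 0.0714 to 0.350), while Cd74, C1qa, Folr2, Tnf and Nlrp3 did; Apoe went from 1.81 ± 0.36 SE to 1.13 ± 0.42 SE. Genes with a mean under 1 FPKM in 1 group met the filter only through the other group. Of those above, Apoc1, Mefv and Vsig4 no longer passed without a filter (adjusted p = 0.0781, 0.0543 and 0.0906), while Eef1a2, Ccr7, Ccl7, Cd163, Egr1, Lilrb4a and Klk1b11 did.

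**Figure D4:**
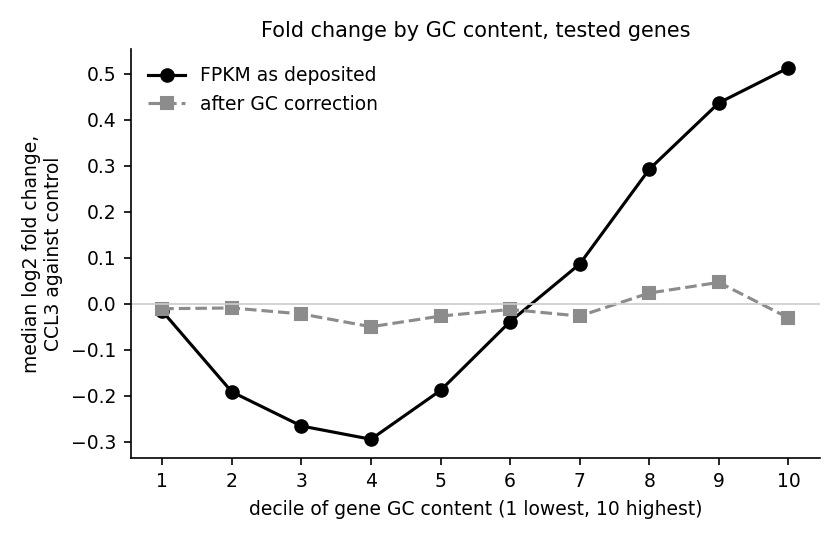
Median log2 fold change of CCL3 against control in deciles of gene GC content, for FPKM as deposited (solid line) and after GC correction (dashed line). As deposited, the median was -0.29 in decile 4 and 0.51 in decile 10.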

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

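The GC, length, plain totals and voom settings and the removal of both replicates numbered 3 were chosen after the data had been seen. Where no cause is named below, the cause was not tested. Under pseudocounts of 0.1 and 0.01, median-ratio scaling, quantile normalization, no variance trend, protein-coding genes only, voom and both GC corrections, the total count of genes stayed within 1.5 times of 2990, from 2318 to 3095. It was 4493 with TPM scaling and 4530 with array weights, and 2007 without a filter, 1112 higher and 895 lower. TPM scaling gave 507 higher and 3986 lower genes, plain totals 803 and 3047, since both lower the median fold change of all genes. Lower genes numbered 2127 with array weights and 720 with a mean of at least 5 FPKM, which tests fewer genes. Requiring 2-fold as well left 737, 502 higher and 235 lower. Leaving out 1 library gave 1128 to 3142 genes, 689 to 1865 higher and 439 to 1277 lower.

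Lists past the threshold numbered 4, but 11 without a filter, 1 with at least 5 FPKM, 2 with array weights, 10 with fry, 0 with an estimated correlation (camera, where 2 had an unadjusted p under 0.05), and 2 to 8 without 1 library. Adjusted p values of the lists follow. Complement had 0.233 with at least 5 FPKM, 0.0532 with median-ratio scaling, 0.263 after quantile normalization, 0.120 with array weights, 0.662 with an estimated correlation and 0.0191 to 0.101 without 1 library. The liver X receptor list had, in the same order without median-ratio scaling, 0.249, 0.117, 0.120, 0.662 and 0.0117 to 0.123, with 0.0525 after GC correction and 0.0510 without both replicates numbered 3. Cell cycle had 0.172 with at least 5 FPKM, 0.880 with an estimated correlation, 0.346 with fry and 4.53e-08 to 0.0666 without 1 library. Mitochondrially encoded genes lost their call only with an estimated correlation (0.662). MHC class II passed without a filter (0.0222), with TPM scaling (0.0295), plain totals (0.0330) and fry (0.0358), and ranged over 0.0117 to 0.182 without 1 library. MHC class I passed without a filter (0.00598) and with fry (0.0154), and ranged over 0.0334 to 0.143 without 1 library.

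Libraries with the same replicate number did not deviate together in every case (correlations of -0.0628, 0.387 and 0.503 across genes). Whether the numbers pair the samples therefore stays open. Only 3 of 6 libraries correlated best with their own number, which does not show pairing. CCL3 replicate 2 correlated more with control replicate 1 (0.413) than with control replicate 2 (0.387). The replicate block raised the count to 3897 and that of risen cell cycle genes to 14, and left 2 lists, with adjusted p 0.0533 for complement and 0.0862 for the liver X receptor list, or 0.0567 with GC correction as well.

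Of 137 genes that the naming rule picked and that passed, 137 kept their call with pseudocounts of 0.1 and 0.01, median-ratio scaling, array weights, no variance trend and the block, 93 without a filter on low values, 109 with GC and length correction, 106 with TPM scaling, and 92 (without control replicate 2) to 130 (without control replicate 3) without 1 library, of those still tested. Signs turned after quantile normalization for Aldoa (-0.0447), Cd68 (-0.138) and H2-K1 (-0.00841), and with TPM scaling for Ticam1 (-0.0171). Genes at a few fragments, such as Nos2 and Arg1, could not be compared at this depth.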

Other observations

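The tests of explanations in this part were written after the results they bear on had been seen. The criteria for gene length, for GC-rich genes, for dendritic or B cells, for proliferation and for the ERK list were also revised after the values of those tests had been seen. Genes of bone and matrix turnover rose in part: the osteoclast acid phosphatase gene Acp5 rose from 8.72 ± 0.989 to 33.4 ± 5.84 FPKM (log2 fold change 1.81 ± 0.17 SE, adjusted p = 0.00310, limma) and Atp6v0d2 with it, 2 of 6 tested osteoclast markers, with 2 falls beside them under TPM scaling. In the tumour-associated matrix and angiogenesis list 5 rose and 2 fell of 16, with rises of the protease inhibitor gene Timp1 (1.90 ± 0.29 SE), the membrane protease gene Mmp14 (1.73 ± 0.34 SE) and Ecm1 (0.96 ± 0.14 SE) against the fall of Vegfa. Of NF-kappaB targets 5 rose and 1 fell of 20; Bcl3 (1.06 ± 0.17 SE) and Relb (0.87 ± 0.17 SE) were higher and Nfkb1 (-0.55 ± 0.17 SE) lower. In Toll-like receptor sensing 2 rose and 2 fell of 17, with Tlr8 at 1.27 ± 0.33 SE. In the lysosome list 4 rose and 2 fell of 23, or 3 and 0 when adjusted over the list alone, with Ctsl at 0.95 ± 0.17 SE and Lamp1 at -0.58 ± 0.19 SE. In glycolysis 2 rose and 2 fell of 21, with Pdk1 at -1.11 ± 0.18 SE and Gpi1 at 0.61 ± 0.13 SE. Ribosomal protein genes split, 10 rose and 9 fell of 27, or 12 and 10 when adjusted over the list alone, with Rps14 at 1.48 ± 0.22 SE and Rpl5 at -1.53 ± 0.28 SE. After GC and length correction Bcl3, Relb, Nfkb1, Ecm1 and Lamp1 no longer passed (adjusted p from 0.0584 to 0.267), and the NF-kappaB list had 1 rise and 0 falls, or 0 and 1 after GC correction alone. Rises and falls of the NF-kappaB list were 1 and 6 with TPM scaling and 2 and 3 with plain totals, and of the lysosome list 0 and 7 with TPM scaling and 1 and 4 with plain totals. They were 3 and 3 with TPM scaling and 3 and 3 with plain totals in the matrix list, 0 and 5 with TPM scaling and 0 and 4 with plain totals in Toll-like receptor sensing, 0 and 9 with TPM scaling and 0 and 6 with plain totals in glycolysis and 6 and 15 with TPM scaling and 8 and 14 with plain totals in ribosomal proteins. With FPKM as deposited camera called none of these lists, with adjusted p values from 0.275 to 0.900, while fry called the osteoclast list as higher (adjusted p = 0.0156).

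Some markers of other blood and stromal cells rose. All 3 tested erythroid markers rose, Epor from 0.655 ± 0.344 to 2.81 ± 0.847 FPKM, Tfrc from 1.05 ± 0.607 to 3.43 ± 0.669 FPKM and Hba-a1 from 0.880 ± 0.304 to 3.14 ± 1.23 FPKM, the last with a near-identical copy and Tfrc also used by macrophages. The other 10 of 13 erythroid markers were below the filter, and Epor and Hba-a1 passed it only through their CCL3 levels (adjusted p = 0.0317 and 0.0611 without a filter). Of 5 tested megakaryocyte markers 3 rose, Ppbp (1.72 ± 0.43 SE), Gp9 (1.44 ± 0.30 SE) and Itga2b (1.39 ± 0.17 SE), none above 4.56 FPKM on average. These 3 genes also met the filter only through their CCL3 levels, and without a filter only Itga2b passed (adjusted p = 0.0143, against 0.0809 for Ppbp and 0.0513 for Gp9). Stromal and endothelial markers gave 3 rises of 5, Acta2 (1.16 ± 0.33 SE), Col1a1 (0.82 ± 0.23 SE) and Col1a2 (0.60 ± 0.19 SE), but 0 rises and 1 fall with TPM scaling or plain totals. Col1a2 met the filter only through its CCL3 level and did not pass without a filter (adjusted p = 0.114). The eosinophil granule gene Prg2 rose by 1.54 ± 0.27 SE, 1 of 2 tested in its list, Il7r from 5.72 ± 2.16 FPKM in control by 1.13 ± 0.29 SE, 1 of 1 among T and NK cell markers, and Blnk from 15.4 ± 0.695 FPKM in control by 0.62 ± 0.13 SE, 1 of 3 among B cell markers, neither Il7r nor Blnk passing with TPM scaling or plain totals. Prg2 had 0.246 FPKM in control and met the filter only through its CCL3 level (adjusted p = 0.0333 without a filter). In neutrophil markers 1 rose and 1 fell of 5, S100a8 (1.25 ± 0.31 SE) and Mmp8 (-0.58 ± 0.18 SE). In monocyte markers 2 rose and 2 fell of 7, with 4 rises when adjusted over the list alone and Ly6a the largest fall; rises and falls were 1 and 3 with TPM scaling and 1 and 2 with plain totals. No member passed among 4 nuclear RNA and replication histone genes, though 3 fell with TPM scaling, or among 2 sex-linked genes. After GC and length correction Epor, Hba-a1, Col1a1 and Mmp8 no longer passed (adjusted p from 0.0589 to 0.170), which left 1 of 3 erythroid markers, Tfrc. With FPKM as deposited camera called none of the lists large enough for it, with an adjusted p of 0.111 for megakaryocyte, 0.317 for stromal, 0.900 for neutrophil and 0.900 for monocyte markers. The megakaryocyte list passed as higher with plain totals (adjusted p = 0.0315), TPM scaling (adjusted p = 0.00517), no filter on low values (adjusted p = 0.00598, median log2 fold change 0.35 against 1.39) and fry (adjusted p = 0.0219). Its adjusted p ranged from 0.00517 to 0.662, the latter with an estimated correlation, over the alternatives with at least 5 tested members. A mean of at least 5 FPKM and the removal of CCL3 replicate 3 left too few members for a test.

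GC content separated the genes that rose from those that fell. Across 9212 genes the Spearman correlation of log2 fold change and GC content was 0.399 and Pearson's r 0.349, and the highest GC decile held 451 rises and 16 falls. A candidate explanation is that GC-rich fragments were recovered to a different degree in different libraries: across the 27 ribosomal protein genes, a co-regulated family, fold change and GC content had a Spearman correlation of 0.560 (permutation p = 0.00297, genes not being independent replicates). These genes have many near-identical copies, so the handling of shared reads could have moved them as well. Their split remained once the GC trend over all genes was removed. Rises and falls were 9 and 10 after GC correction and 8 and 10 after GC and length correction, against 10 and 9 before. The trend over all genes therefore does not account for most of their changes. The tables argue against gene length as the whole cause, since with length held fixed the partial Spearman correlation was 0.381 (95% bounds 0.363 to 0.398), and the median within length deciles was 0.395. In the decile of longest genes the correlation was -0.0970, so the criterion first used, a correlation above 0.2 in every decile, would have left length open. The bounds treat genes as independent. A response of GC-rich genes to CCL3 stays open, because treatment and library cannot be told apart here: libraries also deviated from their own group along GC content, with correlations of up to 0.490 in size, yet every CCL3 library lay above every control library on that trend (0.0257 or more against -0.120 or less).

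Among class II genes Cd74, H2-DMa, H2-DMb1 and Ifi30 rose, and H2-Aa, H2-Ab1 and H2-Eb1 did not pass. The difference between these genes was not tested, and the 95% interval of H2-Ab1, 0.02 to 1.09, contained the changes of H2-DMa, H2-DMb1 and Ifi30, while the upper bounds of H2-Aa and H2-Eb1, 0.70 and 0.58, lay below them. The tables argue against GC content and gene length as the whole cause, since 4 of these 4 genes still passed after GC and length correction, with log2 fold changes of at least 0.64 and adjusted p up to 0.0444. More dendritic or B cells in the CCL3 cultures, which would bring H2-Aa, H2-Ab1 and H2-Eb1 as well, stay open. The highest upper 95% bound of these 3 genes was a log2 fold change of 1.09, for H2-Ab1, against a lower bound of 1.07 for Cd74. The bounds of H2-Aa and H2-Eb1 lay below that of Cd74, which weighs against such cells, and the bound of H2-Ab1 did not. All 3 tested dendritic cell markers rose, 1 of them after GC and length correction, Ccr7, which met the filter only through its CCL3 level (adjusted p = 0.0295 without a filter), and so did Blnk among B cell markers. A response of Cd74 and the peptide loading genes to CCL3 remains a hypothesis, since shared reads among H2 genes were not tested.

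Cell cycle genes were higher on average with CCL3. GC content and gene length do not account for this, because the list's median log2 fold change was 0.78 after correction for both, against 0.80 before (camera adjusted p = 0.000430 after correction with the preset correlation). Without correction the call was lost with an estimated correlation (adjusted p = 0.880). That libraries may differ in proliferation regardless of group stays open: the exact two-sided permutation p of the list's mean was 0.3, where 3 against 3 cannot go below 0.1, and control replicate 3 (4.16) lay above CCL3 replicates 1 and 2. The call was lost without control replicate 1 (adjusted p = 0.0666), with a range from 4.53e-08 to 0.880 over all alternatives.

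The fall of Dusp6 and Spry2, both induced by ERK signalling and acting against it, prompted the hypothesis that ERK output was lower in the CCL3 libraries. A list of 16 ERK feedback and target genes was written after the results had been seen, some of its members included. Of its 9 tested members other than Dusp6 and Spry2, 3 fell, Dusp4 (-0.76 ± 0.23 SE), Spred2 (-0.81 ± 0.25 SE) and Egr1 (-0.92 ± 0.18 SE), and 0 rose. The camera p was 0.0205 with the preset correlation and 0.267 with an estimated one, so ERK output may have been lower, but the test does not settle it. With the preset correlation alone, the criterion first used, the list would have passed.

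With 3 libraries per group there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split gave 2990 genes past the threshold and the highest other split 0 (limma), where up to 1200 genes had an unadjusted p under 0.05. That is 1 split of 10 with a count as large. The real split gave 4 lists and the highest other 15, and 6 of 10 splits gave at least 4 lists. The split with 15 lists set control replicates 1 and 3 and CCL3 replicate 3 against the rest, so the number of lists does not set the treatment apart from other splits.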
